A study of Mus musculus with 3 samples.

How the data were processed

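Ribosomal RNA-depleted RNA-seq libraries had been made from the chromatin fraction of mouse bone marrow-derived macrophages of strain C57BL/6J. The cells had been treated with lipid A, the part of bacterial lipopolysaccharide that activates Toll-like receptor 4 (TLR4), at 100 ng/ml for 50 min, per the labels. The 3 libraries formed 1 group and were numbered 1, 2 and 3 as biological replicates in the labels. The labelled amount of starting RNA was 1000 ng for replicate 1, 250 ng for replicate 2 and 500 ng for replicate 3. The labels gave the 3 libraries the same donor code, so the spreads between libraries below may reflect technical as well as biological variation. The p-values below come from permutation across genes and do not measure variation between libraries. Untreated cells and other cell fractions were not analysed here.

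Each library had a gene table and a transcript table in 1 column format and a transcript table in another. The deposited gene and transcript tables in the first format held expected counts, that is, estimated counts that need not be whole, per the file headers. They also held TPM (transcript abundance scaled to a fixed sum) and FPKM values made by the authors, per the file headers. The transcript tables held, as percent, the share of a gene given to each isoform, per the file headers, and this column was not used because the shares were recomputed from TPM. The deposited table in the second format held estimated counts and TPM per transcript, per the file headers, and is called the second quantification. The build was mm10 and the annotation GENCODE M21, per the deposited notes. The aligner, the quantification tools, their versions and the strand setting were not given in the sources used here. All 55536 gene identifiers and all 141862 transcript identifiers were found in the GENCODE M21 annotation (GRCm38), which gave gene names, classes and coordinates.

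Rows that named no mouse gene were left out of library sizes and tests. The phiX174 row held 1.28%, 0.427% and 0.383% of all expected counts in replicates 1, 2 and 3. The 26248 rows named only by a number held 17, 10 and 5 expected counts, and the 96 ERCC spike-in rows held 0. The remaining gene counts summed to 10496703, 17687379 and 14806118 expected counts in replicates 1, 2 and 3, and to 16644525, 30070348 and 25184406 estimated counts in the second quantification. At these depths a gene with 0 counts was compatible with up to 3 counts in a library, which covers counting error only. The tables give no molecular identifiers.

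Gene lists, comparisons, alternatives and the rule for named genes were fixed before the data were examined. The lists held 38 NF-kB primary-response genes, 24 immediate early genes, 30 interferon and interferon-stimulated genes, 26 symbols of late lipopolysaccharide-response genes (25 genes, because Irg1 is an older symbol of Acod1), 25 TLR4 signalling components, 25 macrophage identity genes, 12 alternative activation genes, 18 housekeeping genes, 23 replication and mitosis genes, 20 nuclear long noncoding RNAs, 13 mitochondrially encoded mRNAs, 76 cytoplasmic ribosomal protein mRNAs, 12 symbols of small nuclear and other abundant noncoding RNAs (13 gene identifiers), 6 sex-linked genes and 85 markers of 10 other cell types. The text names the 4 members with the highest and the 2 with the lowest mean TPM of a list, a fixed set of 20 genes, the 10 genes with the highest mean TPM (protein-coding, and of any class), the 10 genes with the largest range between libraries, and the extremes of the isoform comparison. Only part of these is named, and a gene outside the rule is named as chosen after its values were seen. The level of 1 list member on its own is not reported here.

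A gene counted as detected with at least 10 expected counts in each library. Lists were compared as the difference of medians of log2(TPM + 0.1), each gene averaged over the 3 libraries, so folds of genes near 0 are understated. The test was a two-sided permutation of list membership with 100000 resamples, which cannot give a p below 1e-05, with Benjamini-Hochberg adjustment over the 10 comparisons. Genes are not independent replicates, so these p-values describe lists in these libraries. An exact sign-flip test over 3 libraries cannot go below p = 0.25 and was not used. Expected counts were rounded to whole numbers for edgeR 4.0.16 (R 4.3.3), which gave TMM scaling and the biological coefficient of variation from an intercept-only design. Shifts of a list between libraries were medians, over members with a mean of at least 10 counts, of log2 TMM-normalised CPM (counts scaled to a fixed library size, 0.5 added to each count) minus the mean of the 3 libraries. This limit on counts was not part of the plan and was set after shifts of members with at least 10 counts in each library had been seen, because such a minimum removes genes that are low in 1 library. They were set against 10000 random lists of the same size matched on mean expression in 20 bins, as a description with no p-value, because 1 library stands on each side. The range between libraries was counted for genes with a mean of at least 100 expected counts. The retained-intron share was the percent of a protein-coding gene's TPM given to transcripts annotated as retained intron, averaged over libraries.

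Alternatives were other pseudocounts (1 and 0.01), a filter on low counts, FPKM, the second quantification, TPM rescaled over protein-coding and long noncoding genes, means in place of medians, DESeq2 1.42.0 size factors, library totals, other count limits, and leaving out each replicate. The second quantification for detected genes, for the coefficient of variation and for named genes, the coefficient of variation without 3 genes of the ribosomal DNA locus, and leaving out replicates for class shares, list shifts and named genes were added after the data were seen. Scaling by library total moved all genes by 0.20 (log2) in replicate 1, -0.11 in replicate 2 and -0.09 in replicate 3 relative to TMM.

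The procedures were tested on simulated data. For 12191 genes simulated with coefficients of variation of 0.1 and 0.3, edgeR returned 0.100 and 0.298. Among 12167 simulated genes, 200 were lowered in 1 library, and the 4-fold criterion called 5.66% of those lowered 2-fold, 64.0% of those lowered 4-fold and 100% of those lowered 8-fold. In 40 draws of random lists of 30 genes, the list permutation gave p under 0.05 in 2.5% of draws with no difference and in 92.5% with a planted log2 difference of 4. The retained-intron permutation, on 30 of 1000 genes, did so in 7.5% of 40 draws with no difference and in 100% with 25 percentage points planted. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.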

Results

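Chromatin-associated RNA, which is rich in nascent and nuclear transcripts, was profiled in bone marrow-derived macrophages 50 min after 100 ng/ml lipid A. The 3 biological replicates held 10496703, 17687379 and 14806118 gene-level expected counts in replicates 1, 2 and 3. At least 10 expected counts in each library were found for 12167 of 55536 genes, of which 9656 were protein-coding and 1961 long noncoding. No untreated cells were analysed here, so the levels below show which genes were abundant on chromatin at this time and not which were induced. Differences in level were therefore taken between groups of genes within these libraries and between the libraries themselves. Levels of single genes depended on the quantification: of 180 named genes, 86 were more than 1.5-fold higher and 12 more than 1.5-fold lower in the second quantification (0.1 TPM added), among them Nfkbia (351 and 723 TPM), Ikbke (496 and 1055) and Atf3 (99.98 and 284).

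Across the detected genes, replicates 2 and 3 were closest (Pearson r of log2 CPM 0.985 across genes), followed by replicates 1 and 3 (0.969) and replicates 1 and 2 (0.958), with genes not being independent replicates. Between 50.7% and 74.7% of genes with at least 200 counts in a pair differed by more than counting noise.

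NF-kB primary-response genes were the most abundant of the 4 response groups. The median member stood at 196 ± 38.5 TPM (mean ± SD of the 3 library medians), all 38 genes were detected, and 29 exceeded 100 TPM. The most abundant were Tnfaip2, a tumor necrosis factor-induced gene (ENSMUSG00000021281.15, chromosome 12, 111442469 to 111455018 of GRCm38, 2250 ± 632.2 TPM, SD, n = 3), Malt1, which encodes a paracaspase of NF-kB signalling (909 ± 441), Il1b, which encodes the cytokine interleukin-1 beta (682 ± 149.6), and Tnfaip3, which encodes the NF-kB inhibitor A20 (652 ± 116). Nfkbia, which encodes the NF-kB inhibitor IkB-alpha, stood at 351 ± 67.8 TPM, the cytokine gene Tnf (ENSMUSG00000024401.14, chromosome 17, 35199381 to 35202007) at 345 ± 92.9 and the neutrophil chemokine gene Cxcl2 at 436 ± 71.8. The lowest members were the prostaglandin synthase gene Ptgs2 (22.5 ± 6.16) and the chemokine gene Cxcl3 (1.05 ± 0.0872). For the NF-kB genes this order is that of the first quantification. Tnfaip2 and Malt1 were among the 10 most abundant protein-coding genes in the first quantification. So were the myeloid receptor genes Lilr4b (2138 ± 363.4) and Lilrb4a (2072 ± 615), which are close paralogs whose reads may be shared.

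The NF-kB group lay above each group it was set against. Its median was 8.80-fold that of the interferon group (log2 difference 3.14), 11.6-fold that of the TLR4 signalling components (3.54), 11.4-fold that of housekeeping genes (3.51) and 158-fold that of the late lipopolysaccharide-response group (7.30, and 5.89 with only genes of at least 10 counts, where 16 of 25 late genes remained). The permutation p was 1e-05 for each of these, the smallest the permutations can give, and the adjusted p was 1.67e-05. The direction was the same in 3 of 3 libraries for each comparison. The difference from the interferon group ranged from 2.65 in replicate 1 to 3.92 in replicate 2.

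The TLR4 signalling components had a median of 15.9 ± 3.74 TPM and all 25 were detected. Ikbke, which encodes the kinase IKK-epsilon, was the highest (496 ± 100.7 TPM), followed by the lipopolysaccharide co-receptor gene Cd14 (170.2 ± 80.9), the kinase gene Tbk1 (136 ± 15.8) and Irak2 (133 ± 12.4), which encodes a kinase-like protein of the same pathway. The adaptor genes Tab3 (1.40 ± 0.371) and Tirap (0.770 ± 0.285) were the lowest. This order of the components is that of the first quantification. Housekeeping genes had a median of 17.0 ± 0.585 TPM, all 18 were detected, and Eef1a1, which encodes a translation elongation factor (283 ± 4.21), and the actin gene Actb (137 ± 2.01) led them, while the glycolysis gene Gapdh stood at 8.86 ± 1.45.

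**Figure D1:**
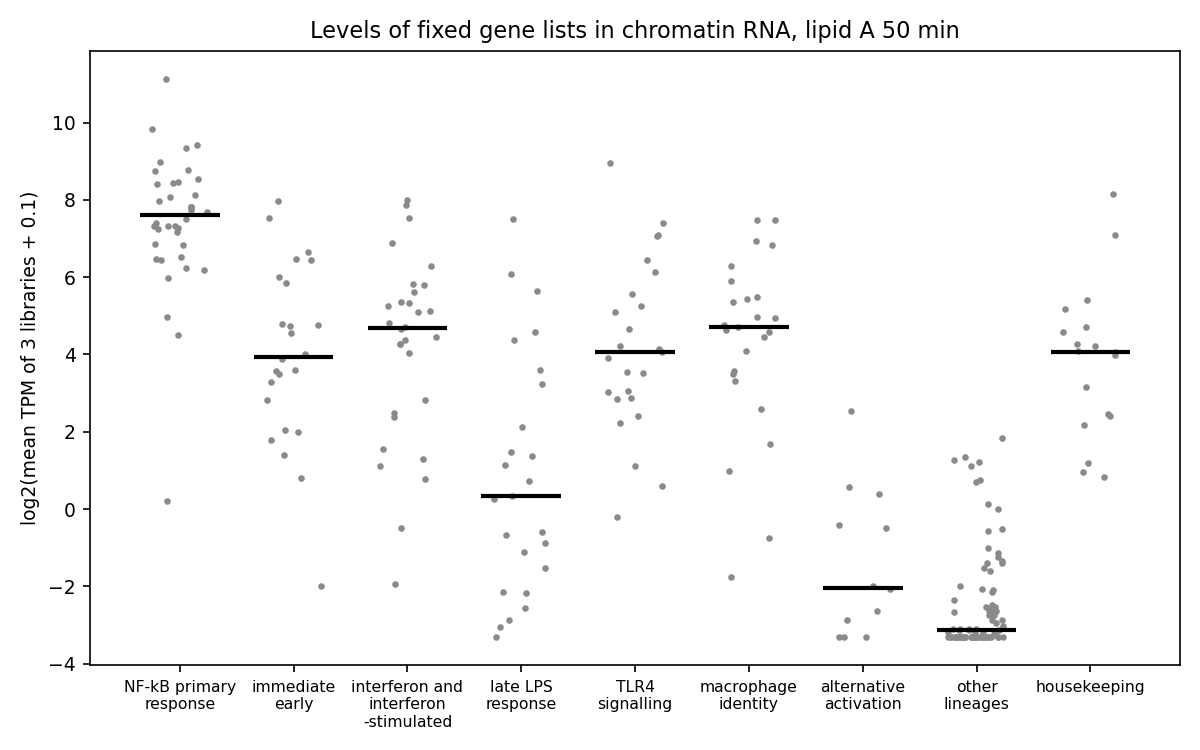
Each grey point is a gene of a list fixed before the data were examined, plotted at log2(mean TPM of 3 libraries + 0.1) on the vertical axis, and the black bars are medians over the list. Of the lists shown, the NF-kB primary-response bar stands highest and the bars of alternative activation genes and of markers of other lineages stand lowest.

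Immediate early genes, whose transcription starts within minutes of a stimulus, stood at a median of 15.9 ± 4.98 TPM, and 23 of 24 were detected. The phosphatase gene Dusp1 (251 ± 54.5 TPM) and the transcription factor genes Klf6 (185 ± 52.9), Atf3 (99.98 ± 51.0) and Csrnp1 (89.1 ± 27.9) were the most abundant. The transcription factor genes Fos (16.0 ± 6.65) and Egr1 (9.71 ± 3.06) were lower, and Egr3 (1.65 ± 0.459) and Fosl1 (0.150 ± 0.110) the lowest. For the immediate early genes, too, this order is that of the first quantification. The group exceeded the late group 12.1-fold (log2 difference 3.60, permutation p = 0.00029, adjusted p = 4.14e-04) in 3 of 3 libraries, and the log2 difference was 2.24 (adjusted p = 0.0276) with only genes of at least 10 counts. It did not differ detectably from the interferon group (log2 difference -0.56, permutation p = 0.355, adjusted p = 0.444). The sign of that difference was negative in replicates 1 and 3 (-1.54 and -0.56) and positive in replicate 2 (0.45).

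Interferon and interferon-stimulated genes had a median of 26.1 ± 14.0 TPM, and 29 of 30 were detected. The highest were Gbp5, which encodes a guanylate-binding protein (257 ± 154.1 TPM), the antiviral gene Rsad2 (235 ± 159.8), the RNA sensor gene Ifih1 (185 ± 125) and Oasl2 (118 ± 44.0). Ifnb1, which encodes interferon beta (ENSMUSG00000048806.4, chromosome 4, 88522025 to 88522774), was present at 16.3 ± 11.6 TPM. The lowest were Igtp (0.613 ± 0.232) and the chemokine gene Cxcl9 (0.160 ± 0.212). This order of the interferon genes is that of the first quantification. The late group was the lowest of the response groups, with a median of 1.08 ± 0.474 TPM and 16 of 25 genes detected. Against 10000 random lists of protein-coding genes (median 0.22 TPM), the late group stood at the percentile of 91.02 (its median of mean TPM was 1.17). It was led by Acod1, which encodes the itaconate-producing enzyme (180.5 ± 121, and 115 for Acod1 without replicate 1), Il1rn, which encodes an interleukin-1 antagonist (67.2 ± 30.5), Il10 (49.4 ± 17.0), which encodes an anti-inflammatory cytokine, and Il12b, which encodes a subunit of interleukin-12 (23.8 ± 24.6). Il6, which encodes interleukin-6 (2.10 ± 1.49), and Nos2, which encodes inducible nitric oxide synthase (0.25 ± 0.207), were near the detection limit.

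The interferon genes were the group that separated the libraries most among the 4 response groups. Their median lay 0.53 (log2) below the mean of the libraries in replicate 2, a shift of -0.53, and 0.27 and 0.31 above it in replicates 1 and 3, and 24 of 29 members were below the mean in replicate 2. None of 10000 random lists matched on expression had a median as low in replicate 2, but this was not particular to the interferon list. The same held for the late genes in replicate 2 and macrophage identity genes in replicate 1, and none was as high for ribosomal protein mRNAs in replicate 2 or immediate early and interferon genes in replicate 3. Cxcl10, which encodes a T cell-attracting chemokine (ENSMUSG00000034855.13, chromosome 5, 92346638 to 92348889), stood at 67.7, 10 and 69.8 TPM in replicates 1, 2 and 3, Rsad2 at 341, 51.4 and 313.5, Ifit1, which encodes an RNA-binding antiviral protein, at 34.8, 5.31 and 34.9, and Ifnb1 at 15.7, 4.95 and 28.2. Protein-coding genes took 22.3%, 16.4% and 20.4% of all TPM in replicates 1, 2 and 3, which widens these drops in TPM. In TMM-normalised counts, 12 of 29 members were at least 2-fold lower in replicate 2 than the mean of replicates 1 and 3 on the log scale. Cxcl10 was 5.46-fold, Ifit1 4.91-fold, Rsad2 4.79-fold and Ifnb1 3.25-fold lower. The antiviral gene Mx1 was not lower (77.1, 84.2 and 69.3 CPM in replicates 1, 2 and 3), nor were the transcription factor genes Stat2 (130, 149 and 148) and Irf7 (37.4, 45.0 and 40.2), which were named after their values were seen. With library totals as the scaling, Stat2 turned lower in replicate 2 by under 10%, and 13 members were at least 2-fold lower. The late genes had the same direction, at -0.40 in replicate 2 with 15 of 17 members below the mean, 0.37 in replicate 1 and 0.06 in replicate 3, where the sign turned with library totals and with the second quantification (-0.03 in both). Il12b stood at 51.2, 3.43 and 16.9 TPM, and at 93.6, 8.76 and 34.2 TMM-normalised CPM, in replicates 1, 2 and 3. The range of the late shift was 0.77, and 0.31 without replicate 2. The range of the interferon shift was 0.85 with all libraries and 0.044 without replicate 2, so replicate 2 set it, and there is no p-value because 1 library stands on each side.

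The other response groups moved less. The NF-kB shift was 0.01, -0.12 and 0.10, and its median in replicate 2 stood at the percentile of 0.49 among matched random lists, with 25 of 38 members below the mean. With library totals the NF-kB shift in replicate 2 was -0.23. The immediate early shift was -0.13, -0.025 and 0.22 in replicates 1, 2 and 3, and its sign in replicate 1 turned with library totals (0.07) and in replicate 2 with the second quantification (0.02). In replicate 2, macrophage identity genes stood 0.23 above the mean, ribosomal protein mRNAs 0.26 and the list of small nuclear and other abundant noncoding RNAs 0.48, and these 3 groups stood lowest in replicate 1, at -0.34, -0.15 and -0.38. The shift of the noncoding list rests on 9 gene identifiers. They are not all separate, because Rn7s1 and Rn7s2 were given the same value. With library totals as the scaling, ribosomal protein mRNAs were at 0.05 in replicate 1 and no longer below the mean. Replicate 2 was also the library with the least RNA input, so input and library cannot be separated here.

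**Figure D2:**
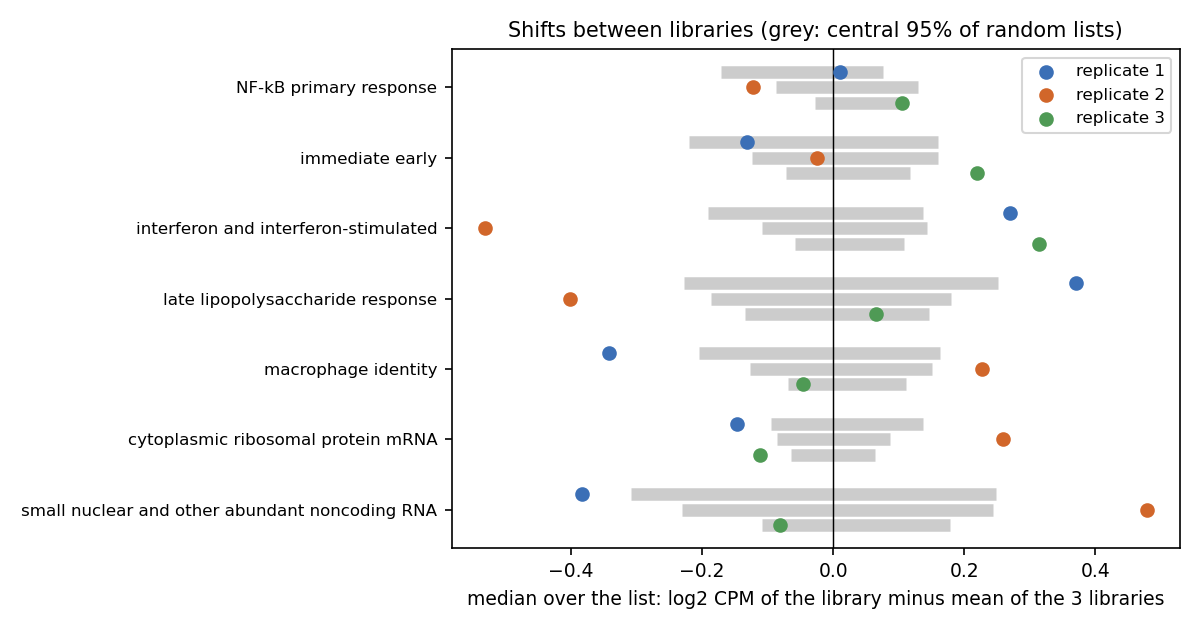
Each point is a library's median shift of a list (horizontal axis, log2 CPM minus the mean of the 3 libraries), with lists on the vertical axis, replicates in color, and grey bars for the central 95% of 10000 matched random lists. The interferon and late lists lie lowest in replicate 2, at -0.53 and -0.40.

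**Figure D3:**
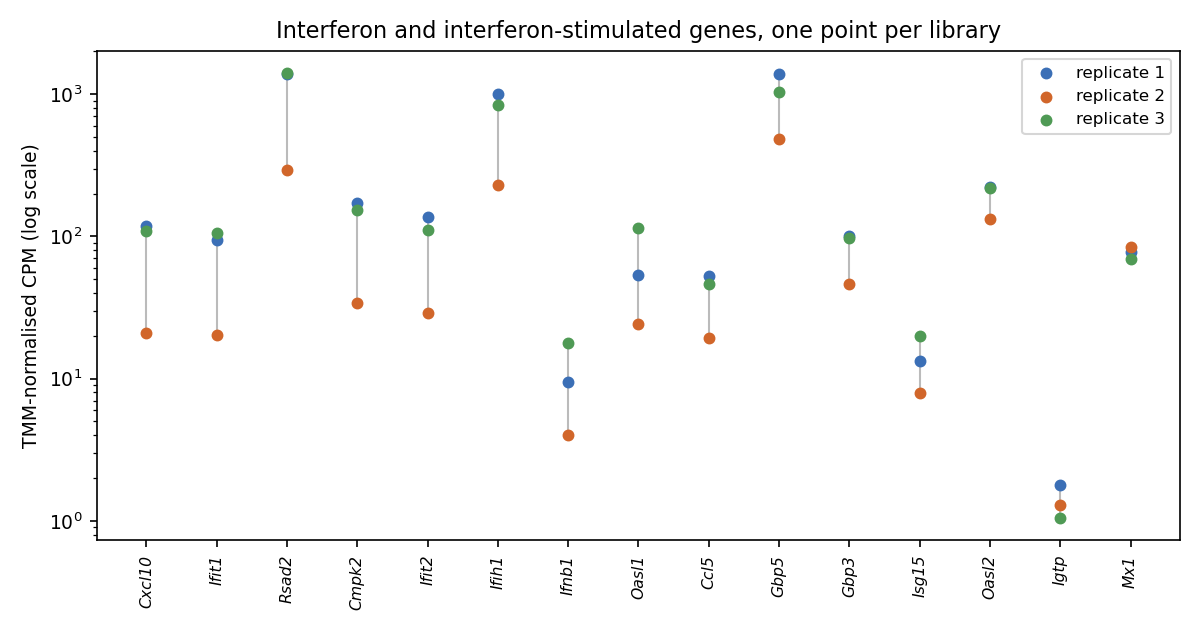
TMM-normalised CPM (log axis) of the interferon-list genes that were at least 2-fold lower in replicate 2 or are named by the rule fixed before the data were examined, 1 point per library, ordered by how far replicate 2 lies below the mean of replicates 1 and 3. Cxcl10 at the left is 5.46-fold lower in replicate 2, and Mx1 at the right was not lower there.

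The libraries carried the profile of macrophages. Macrophage identity genes had a median of 27.3 ± 0.927 TPM and all 25 were detected. Mrc1, which encodes the mannose receptor (179 ± 12.5 TPM), the scavenger receptor gene Msr1 (178 ± 31.7), Csf1r, which encodes the receptor for the macrophage growth factor (122 ± 27.0), and Mertk, which encodes an efferocytosis receptor (113 ± 16.9), led the list. Spi1, which encodes the myeloid transcription factor PU.1, stood at 26.2 ± 10.5, and Cebpa (0.490 ± 0.105) and Ccr2 (0.193 ± 0.115) were the lowest. By the second quantification, Spi1 was at 104.7 TPM and Ccr2, at 3.78, was above Cebpa (0.458). The group exceeded 85 markers of other cell types by 7.79 (log2, 222-fold) and alternative activation genes by 6.80 (112-fold), each with a permutation p of 1e-05, the smallest possible, an adjusted p of 1.67e-05 and the same direction in 3 of 3 libraries. The sizes were set by the pseudocount and the filter, since the differences ranged from 4.01 to 10.42 and from 4.11 to 7.89 over the alternatives.

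Of the 85 markers of other cell types, 9 were detected, 34 had 0 TPM in all libraries and none reached 10 TPM. In the second quantification 32 were detected, 19 were at 0 TPM, and 1 reached 10 TPM. It was the T cell receptor complex gene Cd3d (18.0 TPM against 0 in the first), named after its values were seen. In the first quantification, the highest markers were the lymphoid gene Cd5 (3.47 ± 0.920 TPM) and the dendritic cell transcription factor gene Batf3 (2.46 ± 0.976). They were followed by the platelet chemokine gene Pf4 (2.29 ± 1.97, but 1.16 for Pf4 without replicate 2) and the heme synthesis gene Alas2 (2.21 ± 0.921). By cell type, the detected markers were 3 of 8 for dendritic cells, 2 of 10 for T cells, 1 each for endothelial (of 8), erythroid (of 9), mast (of 9) and megakaryocyte (of 6) markers, and 0 for B cells (of 8), fibroblasts (of 9), natural killer cells (of 7) and neutrophils (of 11). The collagen genes Col1a1 (0, 28 and 21 expected counts in replicates 1, 2 and 3), Col1a2 (1, 25 and 14) and Col3a1 (0, 19 and 12) were the fibroblast markers with the most counts. Of 12 alternative activation genes 3 were detected, with Atp6v0d2, a proton pump subunit gene, the highest (5.68 ± 1.08 TPM) and Retnla and Cdh1 at 0. Replication and mitosis genes had a median of 0.757 ± 0.152 TPM, but Mki67, a marker of cycling cells, stood at 113 ± 21 and the replication clamp gene Pcna at 20.7 ± 12.8, against 0.147 ± 0.0153 for the mitotic kinase gene Plk1. Xist, the RNA that coats the inactive X chromosome, stood at 1026, 980 and 1135 TPM, and the Y-linked genes Ddx3y, Uty and Kdm5d at 0 in all libraries, but at 1.16, 4.09 and 5.28 TPM in the second quantification, so their absence rested on the first. The antisense gene Tsix (0.1 ± 0.0173 TPM) overlaps Xist, and without a stated strand setting its level is uncertain.

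Protein-coding genes took 62.7% ± 4.41 of gene-level counts and long noncoding genes 17.2% ± 3.32 (SD, n = 3). In these shares the 3 genes of the ribosomal DNA-like locus named below were set apart from their annotated classes. Numbers of genes by class kept the annotated classes. Malat1 (chromosome 19, 5795690 to 5802672) and Neat1 (chromosome 19, 5824708 to 5845478), long noncoding RNAs of nuclear speckles and paraspeckles, took 8.76% ± 1.29 and 2.07% ± 0.515, and Xist 1.47% ± 0.173. Counts assigned to 3 genes annotated in a ribosomal DNA-like locus on chromosome 17 (Gm26917, 39843013 to 39846341, with CT010467.1 and Gm42418 up to 39848827) took 9.11%, 22.7% and 21.7% in replicates 1, 2 and 3, and CT010467.1 and Gm42418 overlap on opposite strands, so their split is uncertain. Mitochondrial transcripts took 0.0537% ± 0.0119. Small noncoding genes took 1.72% ± 0.147 of counts but 67.7% of TPM, because TPM divides by very short lengths. The list of small nuclear and other abundant noncoding RNAs, of which 8 of 13 were detected, had a median of 1283 ± 503 TPM, with Rmrp, the RNA of RNase MRP, highest, and Rn7s1 and Rn7s2, copies of the signal recognition particle RNA given the same value, at 11909 ± 2889.

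The list of nuclear long noncoding RNAs as a whole did not differ detectably from ribosomal protein mRNAs or mitochondrially encoded mRNAs. Because no other cell fraction was analysed, these comparisons do not measure nuclear enrichment. Its median was 16.1 ± 3.06 TPM, against 12.4 ± 0.560 for ribosomal protein mRNAs and 23.8 ± 3.44 for mitochondrially encoded mRNAs. The log2 differences were 0.26 (permutation p = 0.551, adjusted p = 0.593) and -0.70 (permutation p = 0.593, adjusted p = 0.593). The first difference was positive in 2 of 3 libraries and the second negative in 3 of 3. Malat1 (18681 ± 8996 TPM), Neat1 (1775 ± 257.5), Xist (1047 ± 79.3) and Mir155hg, the host of microRNA 155 (207 ± 147), were the highest of the 7 members of at least 100 TPM (126 for Mir155hg without replicate 1), while Miat and Mirg were at 0 TPM. With genes of under 10 counts left out, the difference from ribosomal protein mRNAs was 2.48 with an adjusted p of 2e-05 by permutation, so the outcome depended on the 5 of 20 members that were not detected, and over all alternatives the adjusted p ranged from 2e-05 to 0.978. The direction turned in the second quantification (-0.034) and for means (-0.017), and the difference from mitochondrial mRNAs turned with only detected genes (1.35) and for means (0.39), without passing the threshold.

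In the first quantification, primary-response genes gave a larger share of their TPM to transcripts annotated as retained intron than other protein-coding genes. Whether this share reflects such isoforms or unspliced nascent RNA cannot be told from these values. The median share was 56.4% over 34 immediate early and NF-kB primary genes and 41.5% over 6145 others, a difference of 15.0 percentage points (two-sided permutation p = 0.00752), and was positive in 3 of 3 libraries (9.31, 17.9 and 13.8 points). The highest shares were in Dusp1 (96.6% ± 1.85, SD, n = 3), Tnip3 (89.7% ± 2.20) and Nfkb1 (82.3% ± 6.30), which encode a phosphatase, an NF-kB inhibitor and an NF-kB subunit, in Cd83 (84.8% ± 5.60), a surface marker gene of activated cells, and in Sod2 (83.5% ± 2.80), which encodes the mitochondrial superoxide dismutase. The lowest were in Nfkbia (7.97% ± 1.71), the kinase gene Pim1 (8.15% ± 5.46) and Nfkb2 (10.2% ± 0.830). By the second quantification the shares were 93.0% for Dusp1, 32.8% for Nfkbia, which was then not among the lowest, 0.956% for Pim1 and 15.6% for Nfkb2. Against random lists matched on expression the median stood at the percentile of 97.52, and such lists had a median of 48.4%. In the second quantification the difference was 5.69 points (permutation p = 0.393), so the call rested on the first quantification.

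The biological coefficient of variation between the 3 libraries was 0.251 over 12191 genes and 0.160 without replicate 1. A range of at least 4-fold was found in 57 of 6982 genes (0.816%), of which 34 were lowest in replicate 2, 19 in replicate 1 and 4 in replicate 3. The order turned in the second quantification, where 28 were lowest in replicate 2 and 48 in replicate 1, and with library totals it was 52 and 12. Small noncoding genes made up 18 of the 57, but 7 of them, copies of the spliceosomal U1 RNA such as Rnu1a1 (108, 22.03 and 25.6 CPM, named after its values were seen), had the same counts and repeat the same reads. Counted once per set of counts, the 57 genes were 50 and the 34 lowest in replicate 2 were 27. Of 25 protein-coding genes in this set, 15 were lowest in replicate 2 and 9 in replicate 1. Of the 25, 8 belonged to the interferon list, and all 8 were lowest in replicate 2, which restates the interferon shift from the same counts. Among the 10 widest ranges were Matn4 (529, 9 and 53 expected counts in replicates 1, 2 and 3), which encodes an extracellular matrix protein, Slc1a2 (340, 9 and 29), which encodes a glutamate transporter, Rbpjl (892, 97 and 303), which encodes a transcription factor, and Il12b (1123, 143 and 474). The predicted gene B430305J03Rik had 0, 341 and 368 expected counts, but 0 in all libraries in the second quantification, and the RNA gene Rmrp, annotated at overlapping identifiers whose reads may be shared, had 1058, 41592 and 17115 for 1 of them. Without replicates 1, 2 and 3 in turn, 12, 25 and 54 genes ranged at least 4-fold.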

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

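No test was run on the signals in this part, which were found outside the gene-level comparisons and stood above the 3 counts that a count of 0 allows. Expected counts were assigned to phiX174, a phage genome commonly added as a sequencing control, at 135967 in replicate 1, 75816 in replicate 2 and 56920 in replicate 3. In the second quantification, ERCC spike-in sequences took 13, 34 and 33 estimated counts in replicates 1, 2 and 3, while the gene tables listed them at 0. Rows named only by a number took 17, 10 and 5 expected counts.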

How the results depend on the processing

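The 7 list comparisons that passed their permutation test kept direction and side of the threshold under all 10 alternatives, and so did the comparison of immediate early with interferon genes, which did not pass. Their log2 differences ranged from 2.70 to 3.40 for NF-kB against interferon genes, 5.89 to 7.47 for NF-kB and 2.24 to 4.10 for immediate early against late genes, 4.01 to 10.42 for macrophage identity genes against other lineages and 4.11 to 7.89 against alternative activation genes. Of 180 named genes, 115 moved in mean TPM by more than 1 SD in the second quantification, an alternative added later. The second quantification for detected genes and leaving out replicates for list shifts were chosen after the data were seen.

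The 2 comparisons of nuclear long noncoding RNAs changed. Against ribosomal protein mRNAs (0.26) the log2 difference was 2.48 with only detected genes, now past the threshold because members near 0 left the list, -0.034 in the second quantification and -0.017 for means. Against mitochondrial mRNAs (-0.70) it was 1.35 with only detected genes and 0.39 for means. The retained-intron difference of 15.0 points was 5.69 in the second quantification, no longer past the threshold.

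Detected genes (12167) were 8016 at a minimum of 50 counts and 20710 in the second quantification. Genes ranging at least 4-fold (57) were 136 at a mean of 30 counts, which tests more genes, 17 at 1000, which tests fewer, 94 in the second quantification and 12 to 54 with a replicate left out. The coefficient of variation (0.251) was 0.160 to 0.309 with a replicate left out.

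With library totals as the scaling, the range of the median shift between libraries (log2) was 0.44 for NF-kB primary genes, 0.28 for TLR4 components, 0.33 for dendritic cell markers, 0.26 for macrophage identity genes, 0.59 for mitochondrial mRNAs, 0.44 for nuclear long noncoding RNAs and 0.34 for replication genes. In the second quantification it was 0.11 for NF-kB genes, 0.11 for TLR4 components, 0.37 for alternative activation genes, 1.04 for fibroblast markers, 0.45 for megakaryocyte markers, 0.0998 for mitochondrial mRNAs, 0.24 for markers of other lineages and 0.15 for replication genes.

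With a replicate left out, the lowest and highest ranges were 0.093 and 0.23 for NF-kB genes, 0.014 and 0.054 for TLR4 components, 0.11 and 1.08 for alternative activation genes, 0.034 and 0.41 for ribosomal protein mRNAs, 0.038 and 0.17 for dendritic cell markers, 0.40 and 4.84 for fibroblast markers, 0.049 and 0.25 for housekeeping genes, 0.11 and 0.35 for immediate early genes, 0.044 and 0.85 for interferon genes and 0.31 and 0.77 for late genes. They were 0.27 and 0.57 for macrophage identity genes, 0.47 and 1.04 for megakaryocyte markers, 0.11 and 0.29 for mitochondrial mRNAs, 0.040 and 0.14 for nuclear long noncoding RNAs, 0.14 and 0.62 for markers of other lineages, 0.029 and 0.084 for replication genes and 0.30 and 0.86 for small nuclear and other abundant noncoding RNAs. The fibroblast shift rests on 3 genes of under 30 counts.

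By TPM, shares were 5.54% for long noncoding, 19.7% for protein-coding, 6.35% for ribosomal DNA and 67.7% for small noncoding genes, since TPM divides by length. In the second quantification, pseudogenes took 1.86% and small noncoding genes 1.56%. Where no construction is named, the cause was not tested. No paired analysis was possible because the libraries form 1 group. Genes of few counts, such as Nos2 and Cxcl9, are limited by depth.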

Other observations

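The 3 patterns weighed were chosen after the results were seen, as were the tests of the quantification method and of dilution for the interferon genes, and of transcription past neighboring genes.

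Several single genes, named after their values were seen and not tested as a group, were lowest in replicate 1. In TMM-normalised CPM, Flna, which encodes the actin cross-linker filamin A, was 6.02-fold higher in replicate 2 than in replicate 1, Myh9, which encodes a nonmuscle myosin heavy chain, 5.15-fold, and Thbs1, which encodes the matrix glycoprotein thrombospondin 1, 4.76-fold. In replicate 3 the same genes were 2.26-fold, 1.69-fold and 2.63-fold above replicate 1. The immediate early gene Fosb was 4.88-fold and 8.73-fold above replicate 1 in replicates 2 and 3, and the histone deacetylase gene Hdac5 4.55-fold and 4.54-fold. With library totals as the scaling these folds were smaller and kept their direction, from 3.68-fold for Hdac5 to 4.87-fold for Flna in replicate 2 and from 1.38-fold for Myh9 to 7.14-fold for Fosb in replicate 3. The median shift was -3.09, 1.75 and 1.35 (log2) in replicates 1, 2 and 3 for 3 fibroblast markers of few counts, and its range of 4.84 was 1.04 in the second quantification. For 16 markers of other lineages it was -0.37, 0.25 and 0.11, with 9 below and 7 above the mean in replicate 1, and 4 dendritic cell markers did not share this order (-0.056, 0.071 and -0.094). The actin gene Actb did not share this order, at 171, 206 and 168 CPM.

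Interferon genes were lower in replicate 2 (-0.53, log2), and NF-kB primary genes were lower by less (-0.12), though also below the central 95% of matched random lists. Gene length and GC content, fitted with expression over 13253 genes, left the interferon median at -0.52 (log2) in replicate 2, against -0.53 before and a central 95% of -0.09 to 0.12 for matched random lists, which argues against them as the whole cause. The second quantification gave -0.51, which argues against the quantification method. The interferon median minus the NF-kB median was -0.41 in replicate 2 (permutation p = 0.0003 across genes). Even dilution of newly made RNA, or an evenly weaker response, had been taken to lower both lists alike. That holds only if the response made up the same share of the level in both lists. This share is unknown without untreated cells, so the difference decides nothing about dilution or a weaker response. The late genes fell in replicate 2 too (-0.40, 15 of 17 members below the mean), so the shift was not confined to interferon genes. A slightly earlier harvest, a weaker interferon branch of TLR4 signalling or the smaller RNA input of replicate 2 may each account for the pattern, and these were not tested, because the design holds 1 group and 1 library per amount.

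Outside the fixed lists, 14 protein-coding, long noncoding or pseudogenes were at least 4-fold higher in replicate 1 than in replicate 2, led by Matn4 (76.0-fold), Slc1a2 (48.9-fold) and Rbpjl (12.5-fold). They did not share 1 pattern over the libraries. Peli1 stood at 335, 68.1 and 270 TMM-normalised CPM in replicates 1, 2 and 3, and A630072M18Rik at 33.8, 7.70 and 43.9. These, named after their values were seen, were low in replicate 2 rather than high in replicate 1 alone. Nor are the 14 all separate, because Matn4 overlaps Rbpjl and 2610024D14Rik lies inside Peli1. Matn4 and Rbpjl lie 19087 and 8799 bases past the 3' end of Sdc4 (227 TPM), and Slc1a2 lies 20357 bases past that of Cd44 (520 TPM), within the 50 kb and 100 TPM set for such a neighbor. Only Matn4 is annotated on the strand of its neighbor. Rbpjl and Slc1a2 lie on the opposite strand, so transcription past the neighbor could add counts to them only if the strand of the reads was ignored. Such a neighbor was found for 21.4% of the 14 genes, but these are 3 genes with 2 neighbors that prompted the question, so a comparison with random lists of separate genes decides nothing and transcription running past the end of Sdc4 and Cd44 stays open. Sdc4 and Cd44 themselves were 1.48-fold and 1.36-fold higher in replicate 1, far less than these genes, so a difference in their own level alone does not account for the sizes. In the second quantification 50.0% of the 14 genes kept a 4-fold difference and Matn4 was 8.76-fold higher, so part of the size may come from the quantification method, the strand of the reads was not known, and no biological explanation was tested.

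Another 4036 genes had at least 10 estimated counts in each library of the second quantification and under 1 expected count in all gene tables together, 544 of them olfactory or vomeronasal receptor genes, and took 2.73% of the counts there. The share overlapping a gene detected in both quantifications was 11.2%, against 6.37% of genes detected in neither, a ratio of 1.76. The 2 sets were not matched on gene class or length, and 1476 of 4036 against 4264 of 22456 were protein-coding. The ratio therefore cannot tell whether unspliced RNA of overlapping genes is the source for a part of them. The other 88.8% lie outside such genes. Among those with the most counts, Gm23935, Gm24245 and Gm24270, named after their values were seen, had the same counts. These were 2957, 34364 and 16841 in replicates 1, 2 and 3, so their reads may be shared. Sharing among fewer than 10 genes was not measured. Sequence shared with many other genes was to be judged by a ratio of medians, which was undefined because the median percent of 31-base words found in at least 10 genes was 0.714 for these genes and 0 for genes detected in neither. The means went the other way (2.82 and 12.7) and at first had been read as arguing against shared sequence, a reading withdrawn after the outcome was seen because 53.8% of the 3495 of these genes and 24.3% of the 15286 of the others with enough sampled words held any such word, so it stays open.

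Counts assigned to the ribosomal DNA-like locus were lower in replicate 1 in the second quantification too, at 9.42%, 25.8% and 25.1% in replicates 1, 2 and 3. This comparison and that of RNA input, which 1 library per amount leaves undecided, were first planned as tests of a further pattern and are given as values.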
